A study of Leiocassis longirostris with 6 samples.

How the data were processed

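Spleen messenger RNA was sequenced in 6 libraries from fingerlings of Leiocassis longirostris, the Chinese longsnout catfish: 3 libraries from fish given phosphate-buffered saline (control) and 3 from fish given Aeromonas hydrophila, a Gram-negative bacterium that causes haemorrhagic septicaemia in freshwater fish (infected). Groups were taken from the treatment labels and replicate numbers from the sample titles. Per the labels' protocols, 20 fish per group were injected into the body cavity with 100 µL, RNA was extracted with TRIzol and libraries followed standard Illumina procedures. The titles of the infected libraries carry the mark 12h, read here as the time after injection. The time of the control libraries, and whether a library held 1 fish or several, are not given in the sources used here, so p-values measure only the spread between these libraries.

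A single table held, for each gene and library, a read count and an FPKM value, with a gene length. The deposited read counts are expected counts (estimated counts) per gene with no normalization, per the file headers and their values: between 0.78% and 1.31% of the values per library were not whole numbers, counted as any value with a fraction other than 0 as printed in the table. RSEM 1.3.0, FastQC and DESeq are named in the submitters' processing notes, with no role or order given. The deposited FPKM values are read levels scaled by the authors to gene length and library size, per the file headers. The assembly, the aligner and any filter are not given in the sources used here. No value in the table was 0, and the lowest FPKM was 0.31 in each of the 6 libraries, so a gene below that level in any library was not analysed here. One line held a piece of protein annotation with no gene identifier and was left out of totals and tests, which left 26150 genes. The deposited gene lengths, in bases, were used for checks only.

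Identifiers have the form of an assembled contig cluster and a gene number, and the files used here do not pair them with gene names. No reference genome or name table was used. None of the 1166 entries of the 31 gene lists (pathways and cell type markers) fixed before the data were examined matched an identifier (0 matches). The list tests were therefore not run, markers of other cell types could not be read, and genes are not placed on a chromosome. The rule for naming genes, fixed at the same time, was reduced for that case to the 2 identifiers with the largest rise and the 2 with the largest fall. These were taken among genes past the threshold, with a mean of at least 5 CPM, a library-size-scaled count, and with all 3 infected libraries on 1 side of all 3 controls, a condition met by 411 genes.

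Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr defaults, glmQLFit and glmQLFTest, group as the only term, all 6 libraries). This kept 23212 genes and removed 2938. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as higher or lower. Log2 fold changes are infected over control, and the standard error (SE) of each is the absolute log2 fold change divided by the square root of its quasi-likelihood F. Levels are CPM, counts scaled to library size with the TMM factors, given as mean ± SD over 3 libraries. Log2 CPM values for principal components, library correlations in the tests of control replicate 1, and length trends used a prior count of 2. The test was tried on simulated data: counts for the 23212 genes were drawn from their means, spread and library sizes, with 200 genes changed. At the spread of these libraries it called 1 of 50 genes changed 2-fold, 16 of 50 changed 4-fold, 46 of 50 changed 8-fold and 48 of 50 changed 16-fold. That spread was estimated with control replicate 1 included and given to all 6 simulated libraries alike. Of its 123 calls, 12 were unchanged genes, a larger share than the 0.05 that the threshold names.

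Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile scaling and library totals in the same fit, no filter on low counts, a filter of 10 counts in 3 libraries, the DESeq2 1.42.0 Wald test, limma 3.58.1 with voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a minimum absolute log2 fold change of 1, the replicate number as a block, and leaving out each library. Library weights in limma-voom and the removal of a smooth trend on gene length in each library were added after the data were seen. Library totals lay between 18314449 and 33054191 reads. Counting error is small at that depth for most genes (median counts per gene from 100 to 202), and the spread between libraries sets the precision, with a biological coefficient of variation of 0.39 over the tested genes. That value includes control replicate 1, which stood apart. The SD over genes of its log2 CPM difference from the mean of the other controls was 1.24, against 0.423 between control replicates 2 and 3.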

Results

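The spleen transcriptome of Leiocassis longirostris fingerlings was profiled by RNA sequencing in 3 control libraries from saline-injected fish and 3 libraries from fish injected with Aeromonas hydrophila. The design implies 1 comparison, infected against control, which asks how spleen messenger RNA differed after bacterial challenge. Control replicates 1, 2 and 3 held 25069281, 32541711 and 18314449 reads over 26150 genes, and infected replicates 1, 2 and 3 held 18566326, 21257943 and 33054191 reads. The genes are known here by identifier only, so they are described by level, length, direction and size of change, and not by function.

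The 3 most abundant genes, of 665, 589 and 746 bases, together held 12.9% ± 0.228 of reads in control spleens and 10.7% ± 2.17 in infected spleens (SD, n = 3 each). The first took 5.78% ± 0.394 of reads in controls and 4.43% ± 0.781 in infected libraries. The second took 4.99% ± 0.480 in controls and 3.84% ± 0.697 in infected libraries. The third took 2.10% ± 0.295 in controls and 2.40% ± 0.807 in infected libraries. None of these 3 passed the edgeR quasi-likelihood test, with adjusted p of 0.44, 0.44 and 0.96. The 100 most abundant genes of each library held 26.7% to 33.3% of its reads in 5 libraries and 37.3% in control replicate 1.

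After infection 209 genes were higher and 366 were lower, 575 in all or 2.48% of the 23212 tested (edgeR quasi-likelihood test, adjusted p under 0.05). The higher genes had a median log2 fold change of 2.31, with a middle 50% from 1.78 to 2.84. The lower genes had a median of -2.20, with a middle 50% from -2.66 to -1.81. At least 4-fold changes were found for 137 of the higher and 221 of the lower genes, and at least 8-fold changes for 43 and 58. The smallest absolute log2 fold change among the called genes was 1.10. In every one of the 575 genes the 3 infected libraries all lay on 1 side of the 3 controls, which selection by the test on these libraries favours. Over all tested genes the groups were separated in this way in 7662 genes, or 33.0%, where chance gives 10% on average. Genes are not independent, so the share in 1 grouping of the libraries can lie away from 10% by chance. At an unadjusted p under 0.05 the test counted 5143 genes. The DESeq2 Wald test called 2654 genes, 1077 higher and 1577 lower, with all 575 among them. With libraries scaled by their totals only, edgeR called 181 higher and 220 lower genes.

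The higher genes went from a small to a larger part of the transcriptome. Together the 209 genes held 0.444% ± 0.0703 of reads in control libraries and 2.12% ± 0.252 in infected libraries (SD, n = 3 each). The 366 lower genes held 3.69% ± 0.267 of reads in controls and 1.04% ± 0.129 in infected libraries. Among the higher genes 57 reached a mean of at least 100 CPM in infected spleens, against 9 of them at that level in controls. Among the lower genes 65 had a mean of at least 100 CPM in controls. Control replicate 1 held 0.369% of its reads in the higher and 3.47% in the lower genes. These shares describe genes chosen by the test on the same libraries. The median level over the 6 libraries was 21.0 CPM for higher genes, 10.6 CPM for lower genes and 8.04 CPM for all tested genes. The higher genes had a median length of 1865 bases, the lower genes 1392 bases and all tested genes 1432 bases. These medians include control replicate 1, in which the longest 20% of genes had a median log2 difference of -0.61 from the other 2 controls.

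Genes were named among those past the edgeR threshold with a mean of at least 5 CPM and separated groups. Among them the gene with the largest rise, c30030_g1 (1816 bases), increased 55.3-fold. It stood at 13.3 ± 2.99 CPM in controls and 736 ± 142 CPM in infected spleens (SD, n = 3 each), a log2 fold change of 5.79 with an SE of 0.34 and an edgeR adjusted p of 0.0032. Its read counts were 334, 448 and 198 in control replicates 1 to 3 and 16955, 12970 and 25604 in infected replicates 1 to 3. The gene with the next largest rise, c90283_g2 (2192 bases), increased 45.1-fold, from 2.67 ± 1.95 to 119 ± 39.8 CPM, with a log2 fold change of 5.50, an SE of 0.60 and an edgeR adjusted p of 0.012.

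Among the same genes the one with the largest fall, c139995_g1 (1614 bases), went from 119 ± 51.4 CPM in controls to 2.40 ± 1.70 CPM in infected spleens (SD, n = 3 each). Its log2 fold change was -5.64 with an SE of 0.63 and an edgeR adjusted p of 0.012, a 49.8-fold fall. Its control counts were 1221, 5049 and 2870 and its infected counts 25, 95 and 54. The next among these genes, c107175_g2 (948 bases), fell 22.7-fold, from 10.9 ± 5.95 to 0.497 ± 0.425 CPM, with a log2 fold change of -4.50, an SE of 0.74 and an edgeR adjusted p of 0.031. Its infected counts were 19, 6 and 8. In both of these genes control replicate 1 was the lowest of the 3 controls, at 60.2 and 4.19 CPM. The call of c107175_g2 was lost when any 1 library other than control replicate 1 was left out, with an edgeR adjusted p up to 0.15. The calls of c90283_g2 and c139995_g1 were lost when any 1 infected library was left out, with edgeR adjusted p up to 0.084 and 0.10.

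**Figure D1:**
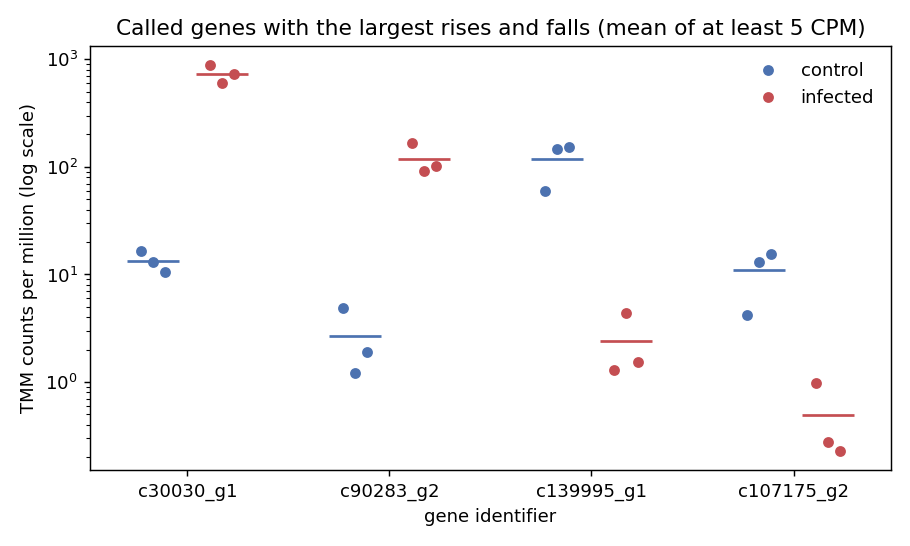
TMM-scaled CPM (log axis) of the 4 named genes in each library, controls in blue and infected in red, with horizontal lines at the group means. The infected libraries of c30030_g1 lie between 596 and 881 CPM and its controls between 10.5 and 16.5 CPM, and for all 4 genes the groups do not overlap.

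The libraries of each group were compared before they were averaged. Control replicates 2 and 3 had a Spearman correlation of 0.988 across genes, and the infected libraries correlated at 0.965 to 0.979 with one another. Control replicate 1 correlated at 0.899 and 0.890 with the other controls and at 0.841 to 0.886 with the infected libraries, below every pair among the other 5 libraries, of which the lowest was 0.936. Genes are not independent replicates, so these values describe the libraries. The first principal component of log2 CPM held 56.5% of the variance and set control replicate 1, at 156, apart from the others. Control replicates 2 and 3 lay at 4.81 and 7.73 on it, and the infected libraries between -84.1 and -32.7. On the second component, with 26.9% of the variance, control replicates 2 and 3 lay at -63.9 and -83.0, infected replicates 1 to 3 at 48.2, 34.3 and 22.4, and control replicate 1 at 42.1. No pair of libraries agreed within sampling noise, as 1 library sequenced or deposited again would: the closest, control replicates 2 and 3, differed by a chi-square of 18.0 per degree of freedom, where sampling noise alone gives about 1. Separate libraries made from the same RNA are not excluded by this.

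**Figure D2:**
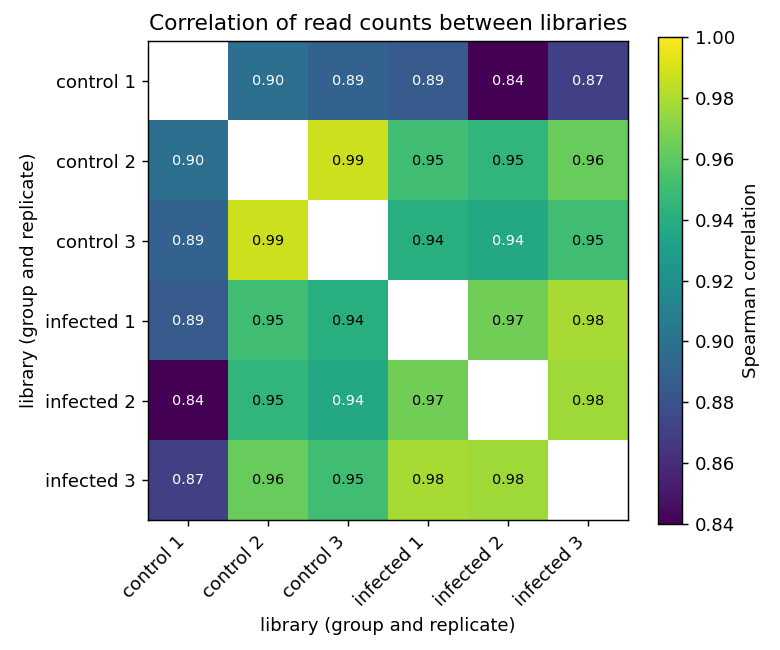
Spearman correlation of read counts over 26150 genes for each pair of libraries, named by group and replicate. Control replicate 1 has values of 0.84 to 0.90 with the other 5 libraries, whose own pairs lie at 0.94 or above.

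The number of genes called rested on which libraries were compared. Without control replicate 1 the same edgeR test called 3259 genes, 1495 higher and 1764 lower, and 574 of the 575 genes called with all libraries were among them in the same direction. Without control replicate 2 it called 34 genes and without control replicate 3 it called 43. Without infected replicate 1, 2 or 3 it called 6, 2 and 4 genes, all of them higher in infected spleens, with 4287, 3456 and 3529 genes at an unadjusted p under 0.05. In control replicate 1 long genes were low against the other 2 controls. The median log2 difference was 0.55 in the shortest 20% of genes (202 to 719 bases) and -0.61 in the longest 20% (2763 to 27127 bases). The median infected-to-control log2 fold change over the same length classes was -0.32 and 0.21 with all libraries, and the median log2 difference of infected libraries from control replicates 2 and 3 alone was -0.096 and 0.039. Removing each library's length trend, a setting chosen after the data were seen, raised the count of called genes to 904, 326 higher and 578 lower.

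**Figure D3:**
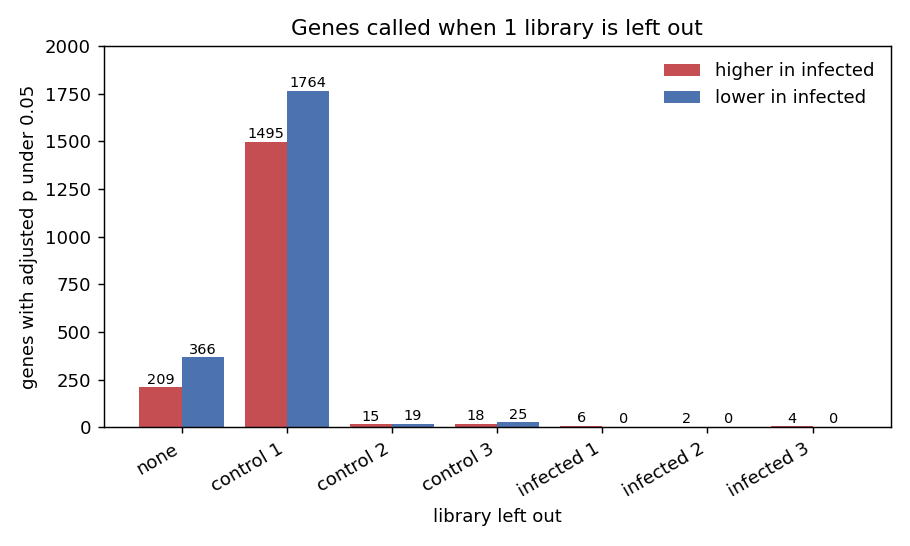
Number of genes with an edgeR adjusted p under 0.05 that were higher (red) or lower (blue) in infected spleens, with all 6 libraries (none) and with each library left out. The counts rise to 1495 and 1764 without control replicate 1 and fall to 25 or fewer without any other library.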

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

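With all 6 libraries, the counts of 209 higher, 366 lower and 575 changed genes stayed within 1.5 times under DESeq2 size factors, upper-quartile scaling, both filters on low counts, limma-voom, limma on both FPKM scales and the fold minimum of 1, which removed no gene. With library totals only, 220 genes were lower, and the median log2 fold change of all genes moved from -0.04 to 0.06. That setting called 401 genes, 374 of them among the 575. It leaves out the TMM factors, which were 0.810 for control replicate 1 and between 1.02 and 1.06 for the other libraries. The DESeq2 Wald test called 2654 genes, 1077 higher and 1577 lower, all 575 among them. The causes of these counts were not tested. Leaving out 1 library gave 2 to 1495 higher, 0 to 1764 lower and 2 to 3259 changed genes, the most without control replicate 1. Without control replicates 2 and 3 edgeR called 34 and 43 genes and without infected replicates 1 to 3 it called 6, 2 and 4. Each test had 5 libraries, so the smaller number does not account for the rise. In settings added after the data were seen, limma-voom with library weights called 6170 genes, 2796 higher and 3374 lower, and gave control replicate 1 a weight of 0.121 against 0.616 to 2.73 for the others. Removal of the length trend gave 904, 326 and 578, and 3622, 1729 and 1893 when control replicate 1 was also left out. The replicate block called 792 genes, 306 higher and 486 lower, 511 of them among the 575. Deviations from the group means correlated at 0.36, 0.24 and 0.03 for equal numbers 1, 2 and 3. Infected replicate 1 correlated at -0.34 and -0.31 with control replicates 2 and 3. Infected replicate 2 correlated best with control replicate 3, at 0.27. Control replicates 2 and 3 were too alike for these values to tell whether equal numbers pair the libraries. The 4 named genes kept their direction in all 20 alternatives. Of these, c30030_g1 passed in all 20 (log2 fold change 5.65 to 5.99), c90283_g2 in 17 (5.01 to 6.30) and c139995_g1 in 17 (-6.38 to -4.93). The gene c107175_g2 passed in 15 (-5.41 to -3.20), and all exceptions were libraries left out. Changes under 4-fold were mostly below what 3 libraries per group could show at this spread. The alternatives for gene lists were not run, because no identifier matched a list.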

Other observations

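All tests in this part were chosen after the results they bear on had been seen. The 575 changed genes carried 545 different contig cluster numbers in their identifiers. Of these clusters, 27 held more than 1 changed gene, and in 26 of the 27 the changed genes went in 1 direction. The number of separate loci behind the count is therefore not known from the files.

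Other splits of the 6 libraries into 3 and 3 were tested in edgeR. Of the 10 splits, 1 (the real one) called 575 genes, and the highest count in the other 9 was 0, with 156 to 1308 genes at an unadjusted p under 0.05. Each of the other 9 mixes infected and control libraries on both sides, so a difference between the groups adds to the spread within each side. The 0 calls there therefore do not measure what chance alone would give. With 10 splits a share under 0.05 cannot be reached.

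Control replicate 1 stood apart from the other 5 libraries, and 2497 of the 23212 tested genes differed more than 4-fold between it and the mean of the other 2 controls. The tables argue against a trend on gene length, which partly degraded RNA might give, as the whole cause. With each library's trend removed, the highest correlation of control replicate 1 with any library rose from 0.870 to 0.901 on log2 CPM. The least similar pair of replicates among the other libraries had 0.957 after removal. The trend held 11.1% of the variance of the differences of control replicate 1 from the other controls. A wrong label on an infected library like the other 3 is argued against too by log2 CPM correlations. Control replicate 1 had at most 0.855 with an infected library, against at least 0.958 for infected pairs. By the same measure it was unlike an ordinary control too, with at most 0.870 against 0.987 for control replicates 2 and 3. These correlations therefore cannot tell which group an outlying library came from. An unusual infected library is not excluded, and the principal components cannot decide. On the second component control replicate 1 lay at 42.1, among the infected libraries (22.4 to 48.2). On the first, at 156, it lay on the far side of control replicates 2 and 3 (4.81 and 7.73) from the infected libraries (-84.1 to -32.7). Scores on the components are uncorrelated by construction, so its place on the second is not separate evidence of likeness to infected libraries. In the genes called without it, positions ran from 0 at the other controls to 1 at the infected libraries. Its median position was 0.391 for higher genes (95% bootstrap interval over genes 0.352 to 0.437) and 0.190 for lower genes (0.144 to 0.220). The intervals do not measure spread between libraries. The same libraries chose these genes and set the scale, so the position cannot decide. Counting noise of low genes was also argued against, since over 10582 genes of at least 10 CPM the highest correlation was 0.714, against 0.893. A different mix of cells, a different state of the fish, a different preparation and a different RNA quality, beyond a length trend, stay open. The genes have no names here, the labels give no batch and no RNA quality value was used. No biological explanation was tested.

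Control replicate 1 may hold part of the pattern seen in infected spleens. The positions of 0.391 and 0.190 rest on 3237 genes, those of the 3259 called without it that were also tested with all 6 libraries, and became 0.467 and 0.145 with the length trend removed. In a simulation with no difference between a further control and the other 2, that control lay at 0.103 and 0.0790, over the 5624 genes called in the simulated counts, a different set of genes. It was drawn once, at the spread of the 5 libraries other than control replicate 1. It thus stands for an ordinary control and not for an outlying one without the infected pattern. This cannot be told apart from a feature shared by control replicates 2 and 3 alone, whose correlation of 0.987 was above that of every infected pair (up to 0.976), so the 3259 genes called without control replicate 1 could include genes in which those 2 libraries are the unusual ones.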
